A study of Dehalococcoides mccartyi with 18 samples.

How the data were processed

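RNA was sequenced from Dehalococcoides mccartyi strain 195, an anaerobic bacterium that respires chlorinated ethenes, in 6 groups of 3 libraries. The labels give a control, a perturbation called salinity 293 and a perturbation called salinity 383, each sampled at 12 h and at 18 h. The unit of 293 and 383 is not given in the sources used here. Per the labels, total RNA was extracted from cells collected on filter membranes. The deposited values are whole-number counts per feature, not normalised, in 1 table with a column for each of the 18 libraries. STAR is named in the submitters' processing notes, without a version, and the reference build, the annotation, the counting step and its use of strand are not given in the sources used here.

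The table held 1679 features, of which 1580 were locus tags made of DET and a number, 46 were tRNA features, 3 were rRNA features and 50 carried EBG numbers. The file does not pair the tags with gene names or products, and no reference table was used here. The gene lists and the genes fixed by name before the data were examined could therefore not be filled, except for the structural RNAs, and the list tests were not run. At most 2 tags that rose and 2 that fell are named. They are the 2 largest rises and the 2 largest falls of each comparison with a control, among genes with an adjusted p under 0.05, treated libraries all on one side of the control libraries, and a mean of at least 50 counts in the higher group.

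The 3 rRNA features were left out of library totals and tests. Libraries were scaled by TMM factors and low features were removed with filterByExpr, which left 1456 features, 85 of the 1679 having a total of 0. One model with a mean for each of the 6 groups was fitted to all 18 libraries with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), and contrasts were tested by the quasi-likelihood test with Benjamini-Hochberg adjustment over the features tested, at a threshold of 0.05. Standard errors (SE) of log2 fold changes were taken from the quasi-likelihood F statistic. The 11 contrasts were fixed before the data were examined, as were these alternatives: RLE size factors, library totals alone, DESeq2 1.42.0, no filter, a filter of at least 50 counts in at least 3 libraries, the replicate number as a block, a minimum absolute log2 fold change of 1, rRNA kept, a fit of the compared groups alone, and each library left out in turn. Values per library are CPM, the counts scaled to the TMM-adjusted library total, and distances and principal components used log2 CPM with a prior count of 2.

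Total counts ran from 7923007 to 9834566 per library. Within groups, pairs of libraries differed by a chi-square of 17.1 to 922 per feature, so no 2 libraries agreed within sampling noise. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. On counts simulated for the comparison of salinity 383 with control at 12 h, with 200 of 1456 genes changed and the spread of all 18 libraries, the test recovered 22% of the genes changed by 1.5-fold, 50% of those changed by 2-fold, 94% by 4-fold and 98% by 8-fold, with 5 false calls among 1256 unchanged genes. Genes were simulated independently and in a single run. In the data, libraries that stand apart from their groups move many genes together, so these rates may not hold there.

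Replicate numbers are shared between groups. The pairing was checked from the deviations of log2 CPM from the group means. All 3 same-numbered pairs correlated above 0.1 across genes for salinity 293 and control at 18 h (0.65, 0.48 and 0.47) and for salinity 383 and 293 at 12 h (0.61, 0.40 and 0.35). Deviations from a mean of 3 sum to 0, so a displaced replicate 1 in both groups gives all 3 values together. Without replicate 1, the differences between replicates 2 and 3 correlated across genes at -0.02 and 0.00 in these comparisons, so the check shows displaced replicate 1 libraries and no pairing of the others. The labels give no pairing. For both comparisons a fit of the compared groups with the replicate number as a block was added.

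Several replicate 1 libraries stood apart from their groups. All libraries were kept in the groups the labels give. After these libraries had been seen, 3 exclusions were added: replicates 2 and 3 alone, 4 libraries left out together (replicate 1 of control at 18 h, of salinity 293 at 12 h and 18 h, and of salinity 383 at 12 h), and 5 libraries left out together (those 4 and replicate 1 of salinity 383 at 18 h). Leaving out libraries because they stand apart shrinks the spread that the test uses, so p-values under these exclusions are too small and their calls are not independent evidence.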

Results

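Transcript abundance was measured in wild-type Dehalococcoides mccartyi strain 195 at 12 h and 18 h after 2 salinity perturbations, named 293 and 383 in the labels, and in control cells of both times. Each of the 6 groups had 3 libraries, with total counts between 7923007 and 9834566. A single locus tag was the most abundant feature in all 18 libraries and took 8.09% to 17.8% of the counts.

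The first principal component held 62.9% of the variance and ran from the control to the treated libraries, with exceptions that all carried replicate number 1. Replicate 1 of control at 18 h scored 6.06, whereas replicates 2 and 3 of that group scored -20.89 and -19.29. Replicate 1 of salinity 293 at 12 h scored -18.14, against 6.31 and 6.13 for the other 2 libraries of its group. Replicate 1 of salinity 293 at 18 h scored 17.22 against 1.87 and 1.33, and replicate 1 of salinity 383 at 12 h scored 1.92 against 18.65 and 15.97. Replicate 1 of salinity 383 at 18 h stood apart on the second component, with a score of 28.94 against -3.13 and -4.60. The comparisons below use every library as labelled, and these 5 libraries enlarge the spread in each of them.

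**Figure D1:**
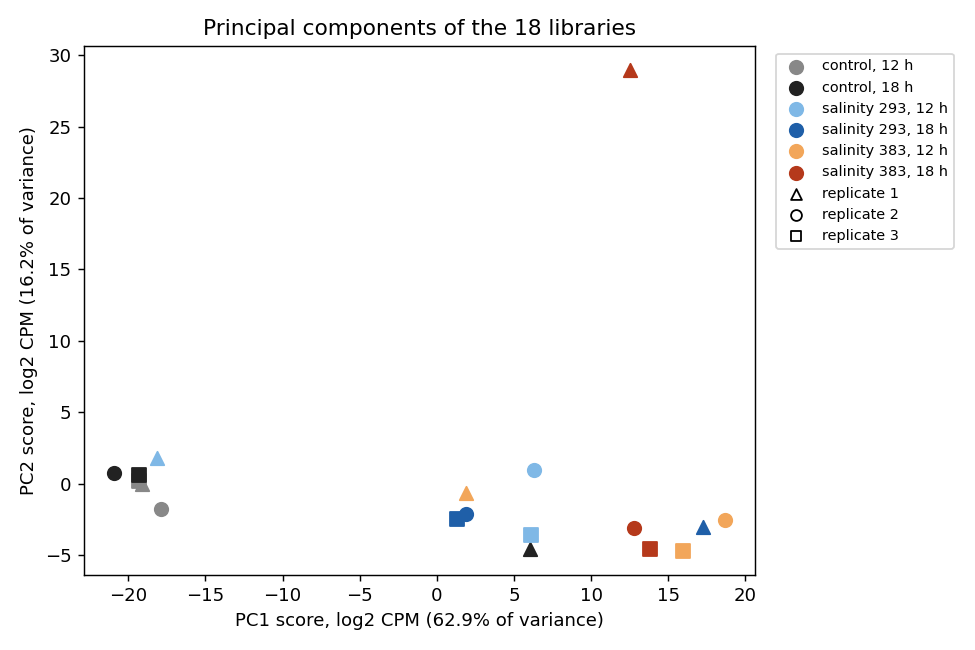
Scores of the 18 libraries on the first and second principal components of log2 CPM, coloured by group, with the replicate number as the symbol. The control libraries lie between -20.89 and -17.88 on the first component except replicate 1 at 18 h (6.06), and replicate 1 of salinity 383 at 18 h lies alone at 28.94 on the second.

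The comparison of salinity 383 with control at 12 h asked how transcript levels differed 12 h after the perturbation with the higher number. Of 1456 features tested, 264 rose and 203 fell at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). The largest rises that met the naming rule were those of DET0221 and DET0220. DET0221 went from 81.0 ± 16.4 CPM in control to 7449 ± 4009 CPM (SD, n = 3 each), a log2 fold change of 6.52 ± 1.56 (SE, edgeR adjusted p = 0.0215). DET0220 went from 16.5 ± 2.38 to 385.9 ± 141.9 CPM, a log2 fold change of 4.55 ± 1.10 (edgeR adjusted p = 0.0215). The largest falls were those of DET0629, from 449.8 ± 3.67 to 41.5 ± 13.1 CPM (log2 fold change -3.44 ± 0.89, edgeR adjusted p = 0.0216), and DET0908, from 266.9 ± 57.8 to 32.4 ± 2.78 CPM (log2 fold change -3.04 ± 0.80, edgeR adjusted p = 0.0216). The groups did not overlap for 64.5% of features, where chance gives 10% for 3 libraries against 3. This share was 32.9% for salinity 383 at 18 h, 25.0% and 15.5% for salinity 293 at 12 h and 18 h, 10.9% and 5.36% for salinity 383 against 293 at 12 h and 18 h, and 7.01% for control between times.

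Among the 39 tRNA features tested, 15 rose and 1 fell in this comparison, and adjusted over the list alone 17 rose and 1 fell. tRNA took 0.102% ± 0.0140 of the counts after salinity 383 and 0.0623% ± 0.00742 in control at 12 h (SD, n = 3 each), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows, and an adjusted p of 0.2 (Benjamini-Hochberg) over the family of 8 comparisons of shares. These tests of shares were not planned. rRNA took 0.291% ± 0.136 after salinity 383 and 0.874% ± 0.697 in control at 12 h (exact permutation p = 0.2, adjusted 0.267). At 18 h the order was the opposite, with 0.628% ± 0.465 after salinity 383 and 0.298% ± 0.0495 in control (exact permutation p = 0.4, adjusted 0.4). The size of both differences leaned on single libraries, replicate 1 of control at 12 h with 1.65% and replicate 3 of salinity 383 at 18 h with 1.15%, where the other 2 libraries of that group had 0.492% and 0.247%. In replicates 2 and 3 at 12 h the order was kept, with means of 0.216% after salinity 383 and 0.488% in control. The other 5 comparisons of shares, salinity 293 included, had adjusted exact permutation p between 0.2 and 0.343.

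The fold changes of the named tags moved little when single libraries were left out. The tags were picked from these same libraries for large changes and groups that did not overlap, so this is partly built in. The number of features past the threshold depended on single libraries. It was 0 without replicate 1, 2 or 3 of control at 12 h, and 0 without replicate 2 or 3 of salinity 383 at 12 h, and it was 563 without replicate 1 of salinity 383 at 12 h. The 4 named tags missed the threshold under the same 5 omissions, with edgeR adjusted p between 0.0566 and 0.0921 and log2 fold changes of 6.28 to 6.70 for DET0221, 4.31 to 4.66 for DET0220, -3.44 to -3.26 for DET0629 and -3.13 to -2.85 for DET0908. The fit of the 2 groups alone called 773 features, and scaling by library totals alone gave 270 rises and 124 falls, a share of rises of 68.5% in place of 56.5%.

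**Figure D2:**
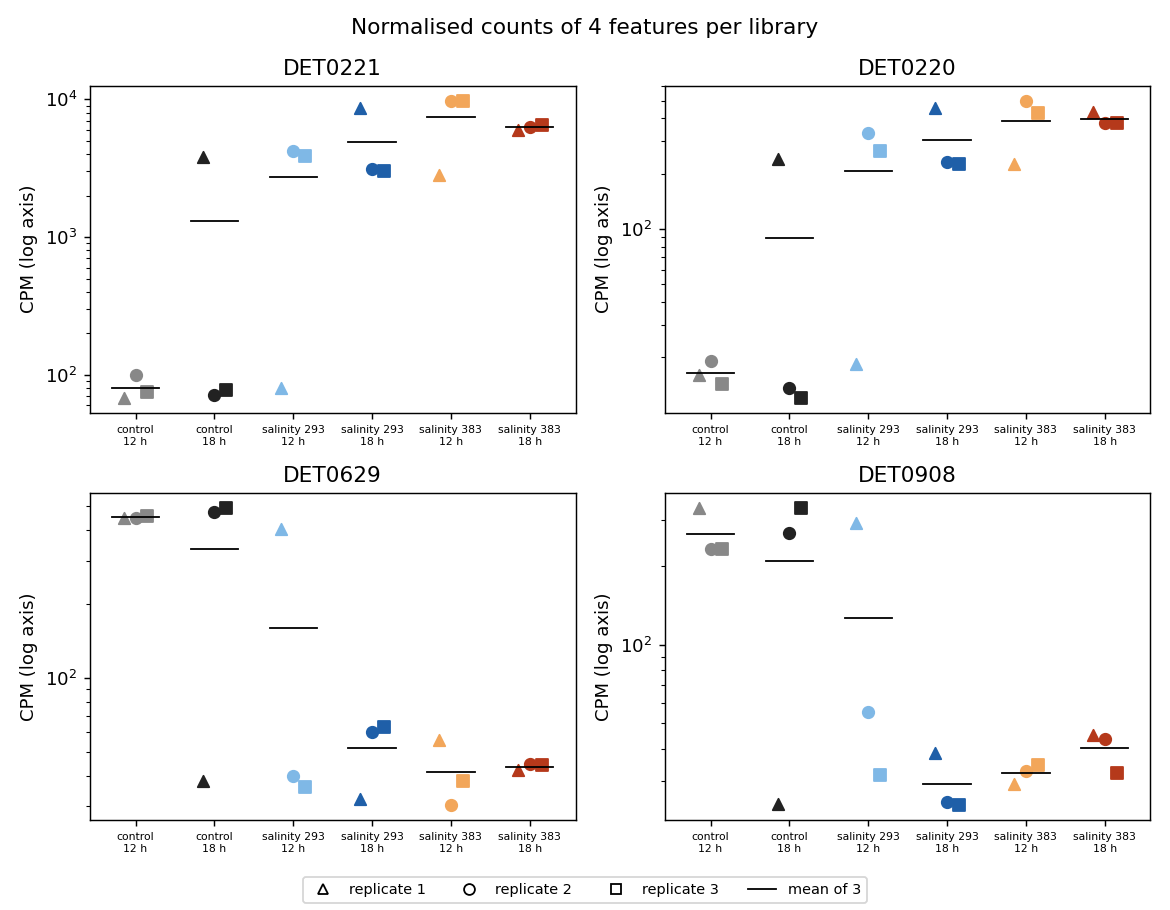
CPM on a log axis for DET0221, DET0220, DET0629 and DET0908 in each library, by group, with the replicate number as the symbol and a line at the mean of 3. At 12 h the salinity 383 libraries lie apart from the control libraries for each tag, while replicate 1 of control at 18 h (3794 CPM for DET0221) and replicate 1 of salinity 293 at 12 h (80.1 CPM) lie away from their groups.

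At 18 h, salinity 383 against control called 0 features with edgeR, with 575 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0501. DESeq2 called 372, of which 173 rose and 199 fell. DET0221 had a mean of 6280 ± 262.7 CPM after salinity 383 and 1315 ± 2148 CPM in control (SD, n = 3 each), the control mean resting on replicate 1 with 3794 CPM beside 71.2 and 78.1 CPM in replicates 2 and 3. Without replicate 1 of control at 18 h, 579 features were called, 338 higher and 241 lower. The median log2 fold change of the 39 tRNA features was 0.80, with 0 called over all features, and adjusted over the list alone 14 rose and 2 fell.

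Averaged over both times, salinity 383 against control called 762 features, of which 424 rose and 338 fell (edgeR), and DESeq2 called 810. Among the tRNA features 21 rose and 2 fell. The count lay between 599 and 931 when each of the 12 libraries was left out in turn.

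Salinity 293 against control called 0 features at 12 h and 0 at 18 h with edgeR, with 208 and 202 at an unadjusted p under 0.05. DESeq2 called 11 and 4. DET0221 stood at 2732 ± 2304 CPM after salinity 293 at 12 h, where replicate 1 had 80.1 CPM and replicates 2 and 3 had 4237 and 3879 CPM. At 18 h it stood at 4927 ± 3214 CPM (SD, n = 3 each), with 8638 CPM in replicate 1 and 3099 and 3045 CPM in replicates 2 and 3, whose mean was 3072 CPM. At 18 h, 220 features were called without replicate 1 of control. The 2-group fit with the replicate number as a block called 183, whereas that fit without the block and the 18-library fit with it called 0 each. The block in the 2-group fit was added after the data were seen. It takes up the displacement of replicate 1 and so shrinks the spread, and its p-values may be too small. Averaged over both times 1 feature fell, against 247 called by DESeq2, 473 without replicate 1 of control at 18 h, 414 without replicate 1 of salinity 293 at 12 h, 7 without replicate 2 of control at 12 h, and 0 under each of the other 9 omissions. Adjusted over the list alone, 16 tRNA features rose and 0 fell in that average, while 0 rose and 0 fell at 12 h or at 18 h alone.

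With replicates 2 and 3 alone, an exclusion chosen after replicate 1 had been seen to stand apart, salinity 293 called 787 features at 12 h and 742 at 18 h, and salinity 383 called 989 and 978. With the 4 libraries that lay near other groups left out the counts were 412, 289, 702 and 682, and with 5 left out they were 872, 789, 1039 and 1004. These p-values are too small, because the libraries were left out for standing apart. Of the 467 calls for salinity 383 at 12 h, 464 were among the 989, all with the same direction. Both fits hold the same replicates 2 and 3, so this overlap is not independent evidence.

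Salinity 383 against salinity 293 tested the difference between the perturbations. It called 0 features at 12 h and 0 at 18 h with edgeR, with 167 and 63 at an unadjusted p under 0.05, and DESeq2 called 0 and 1. At 12 h the 2-group fit with the replicate number as a block called 206, with the same limit as for salinity 293 at 18 h. With replicates 2 and 3 alone the counts were 513 and 377, with 4 libraries left out 75 and 84, and with 5 left out 549 and 428.

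Control at 18 h against control at 12 h called 0 features with edgeR and 0 with DESeq2, with 14 at an unadjusted p under 0.05, and the count stayed at 0 when each library was left out and under the 3 exclusions. The test of whether the response differed between 18 h and 12 h called 0 features for salinity 293 and 0 for salinity 383 with both tools, with 12 and 20 at an unadjusted p under 0.05.

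The log2 fold changes of the perturbations correlated across genes, which are not independent replicates, with r = 0.88 at 12 h and r = 0.85 at 18 h. Both share their control libraries, and unchanged groups simulated against those controls gave 0.51 and 0.49. The covariance was 0.410 at 12 h and 0.292 at 18 h, and the simulated covariance was 0.054 and 0.052. The simulated groups were independent, whereas same-numbered libraries of salinity 383 and 293 at 12 h, and of salinity 293 and control at 18 h, deviated together through replicate 1. The simulated values leave this out. Joint deviations of the treated groups can raise the correlation and covariance at 12 h without an effect. Here replicate 1 of salinity 293 and of salinity 383 at 12 h both lay toward the control libraries on the first component, at -18.14 and 1.92. With replicates 2 and 3 alone, r was 0.91 at 12 h and 0.92 at 18 h, and the covariance was 0.659 and 0.569, with simulated covariances of 0.024 and 0.022. The covariance at 12 h was thus larger without the replicate 1 libraries. This argues against their joint deviation as the source of the excess there, though the exclusion was chosen after the data were seen. With all libraries no feature was called for salinity 293 alone at either time, so there was no overlap of calls to count. With replicates 2 and 3 alone, where p-values are too small, 366 features rose and 339 fell in both at 12 h. Independent lists of those sizes share 133.3 and 133.2. Simulated unchanged groups shared at most 1. That value is low by construction, since neither simulated group differs from control, so it does not bear on the overlap. At 18 h the counts were 342 and 352, against 122.8 and 125.8. Part of the excess may come from the shared controls, which are too few to be split.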

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

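The exclusions of several libraries and the 2-group blocked fits were chosen after seeing the data; the other alternatives were fixed before. The cause of a change was not tested unless stated. RLE size factors moved no count by over 1.5 times.

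DESeq2 called 11 (salinity 293, 12 h), 4 (293, 18 h), 372 (383, 18 h), 247 (293 averaged) and 1 (383 against 293, 18 h). With rRNA kept, salinity 293 called 2 at 12 h and 5 averaged. Salinity 383 at 18 h called 7 without a filter and 8 under the stricter one. Library totals alone gave 15 for 293 averaged. A minimum log2 fold change of 1 left 225 (383, 12 h), 200 (383 averaged) and 0 (293 averaged), by construction. The compared groups alone gave 773 (383, 12 h) and 0 (293 averaged).

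Leaving out each library in turn gave 0 to 220 (293, 18 h), 0 to 563 (383, 12 h), 0 to 579 (383, 18 h), 0 to 473 (293 averaged), 599 to 931 (383 averaged), 0 to 1 (383 against 293, 18 h) and 0 to 1 (383, difference between times). It gave 0 throughout for 293 at 12 h, 383 against 293 at 12 h, control between times, and the 293 difference between times. The value of 0 for 383 at 12 h came without replicate 1, 2 or 3 of control at 12 h or replicate 2 or 3 of salinity 383. The 1 in the last 2 ranges, and 1 for 383 at 18 h, came without replicate 2 of salinity 383 at 18 h.

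With the replicate block in the 18-library fit, 383 at 12 h called 318, 383 averaged 716, and 293 averaged 0; no other count changed. Same-numbered deviations correlated from -0.37 to 0.65 over 21 pairs, and 2 of 18 libraries correlated best with a library of their own number. In 2-group fits the replicate block gave 183 (293, 18 h) and 206 (383 against 293, 12 h). There it takes up the displacement of replicate 1, so these p-values may be too small.

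Replicates 2 and 3 alone gave 787 and 742 for 293 (12 h, 18 h), 989 and 978 for 383, 992 for 293 averaged, 513 and 377 for 383 against 293, and 4 for the 383 difference between times. With 4 libraries left out these were 412, 289, 702, 682, 591, 75 and 84, with 0 for that difference. With 5 left out they were 872, 789, 1039, 1004, 1028, 549, 428 and 11, with 1151 for 383 averaged and 2 for the 293 difference between times. These exclusions remove libraries that stand apart, which shrinks the spread by construction.

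For the 4 named tags, 201 of the recomputed log2 fold changes stayed on their side of the threshold, 47 passed it, 20 no longer did, and 0 changed sign. DESeq2 gave no adjusted p for DET0221 and DET0629 in the comparisons with a control, so these tags were not checked with it and are not in its counts. The list tests and their alternatives were not run, because no gene names were used. Depth was similar across libraries; in the simulation, recovery at 1.5-fold was 22% with the spread of all libraries and 72% with that of replicates 2 and 3.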

Other observations

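The tests of the replicate 1 libraries and of neighbouring features were chosen after the values they bear on had been seen; the splits with the replicate number as a block were also added later, and the other splits were planned.

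Features listed next to each other in the table changed together. For salinity 383 against control at 12 h, the log2 fold changes of 1376 neighbouring pairs correlated across genes with r = 0.46, and the highest of 1000 shuffled orders gave 0.08. Called features formed 26 runs of at least 4 neighbours with one direction, and the shuffled orders gave at most 6. The longest runs did not exceed the highest of the 1000 shuffled orders, with 8 features that rose against a shuffled highest of 9, and 6 that fell against 7. How many shuffled orders reached such lengths was not counted. DET0220 and DET0221 lay in one such run of 4 that rose. This is consistent with transcription in shared units, a hypothesis that the table alone does not test further.

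Replicate 1 of 5 of the 6 groups lay nearer to replicates 2 and 3 of another group than to those of its own, all but that of control at 12 h. For salinity 383 at 18 h the difference was small, 0.844 to salinity 293 at 12 h and 0.872 to its own group, and this library was far from every group. In root mean square log2 distance, control at 18 h lay 0.297 from salinity 293 at 12 h and 0.746 from its own group, and salinity 293 at 12 h lay 0.314 from control at 12 h and 0.695 from its own. Salinity 293 at 18 h lay 0.234 from salinity 383 at 12 h and 0.539 from its own, and salinity 383 at 12 h lay 0.228 from salinity 293 at 18 h and 0.564 from its own. A shift shared by the 6 replicate 1 libraries is argued against, since their deviations had a median pairwise correlation of 0.04 across genes and a lowest of -0.86. No biological explanation was tested, since the design gives none.

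An exchange of the replicate 1 libraries of salinity 293 at 18 h and salinity 383 at 12 h may account for 2 of these libraries and stays open. Their deviations from replicates 2 and 3 correlated across genes at -0.83. An exchange would bring such a mirror image, but so does displacement in opposite directions between control and treated libraries. Replicate 1 of salinity 293 at 12 h and 18 h gave -0.61, and that of control at 18 h and salinity 383 at 12 h gave -0.57. Pairs displaced in the same direction gave 0.65 and 0.61. Off the axis from control to treated libraries, with own group at -1 and the other at 1, the 2 libraries of this exchange lay at 0.54 and 0.74 (spread of replicates 2 and 3, 0.14), on the other group's side. The rRNA shares of the 2 libraries, 0.105% and 0.443%, did not lie with the other group. Over both times, salinity 293 libraries had 0.0787% to 0.188% and salinity 383 libraries 0.180% to 1.15%. Each share lay in the range of its labelled treatment and outside that of the other, which goes against the exchange. Within control at 12 h rRNA ranged over 1.35 percentage points, so rRNA alone does not settle the question. A first form of this test, on distances that had prompted the explanation, gave a ratio of 0.947 to the distance between replicates 2 and 3 and would have favoured the exchange.

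An exchange of replicate 1 of control at 18 h and salinity 293 at 12 h may account for the other 2 and stays open as well. Their deviations correlated across genes at -0.86, with the same limit as above. Replicate 1 of control at 18 h lay 0.297 from salinity 293 at 12 h and 0.307 from salinity 293 at 18 h. Replicate 1 of salinity 293 at 12 h lay 0.357 from control at 18 h, nearer than its own group (0.695). It lay nearer still to control at 12 h (0.314). The distances thus place 1 library with the treated and 1 with the control libraries, but do not single out this exchange. Off the same axis the 2 libraries lay at -0.51 and -0.87 (spread 0.72), on their own groups' side, but the first lies within the spread and this part holds only 8.88% of the difference between the groups. On the fourth component, with 3.71% of the variance, replicate 1 of salinity 293 at 12 h scored -7.79. The rest of its group scored -8.43 and -3.29, the control libraries 0.25 to 2.16, and replicate 1 of control at 18 h 0.64. On the third component, with 5.1% of the variance, replicate 1 of control at 18 h scored 1.66. The rest of its group scored -3.54 and -3.1, and replicates 2 and 3 of salinity 293 at 12 h 2.27 and 3.96. Replicate 1 of salinity 293 at 12 h scored 0.6, between these groups. The scores on the fourth component thus go with the labels. Those on the first component, and that of replicate 1 of control at 18 h on the third, go with the exchange. The rRNA shares of the 2 libraries, 0.350% and 0.110%, were near those of their own groups. Over both times, control libraries had 0.251% to 1.65% and salinity 293 libraries 0.0787% to 0.188%. These rRNA shares go against the exchange, but rRNA alone does not settle it, for the same reason as above. The tRNA share of replicate 1 of control at 18 h, 0.106%, lay with replicates 2 and 3 of salinity 293 at 12 h (0.103% and 0.104%). The rest of its own group had 0.0549% and 0.0542%. Replicate 1 of salinity 293 at 12 h had a tRNA share of 0.0810%, between these groups. A first form of this test, a score on 66 genes, gave 0.28 against -0.19 to 0.14 in 5 control libraries and was replaced after that result was seen, and the bound of the second form was widened to both libraries, and to the rRNA range within groups, after its result was seen.

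Replicate 1 of salinity 383 at 18 h had 191 features at least 2-fold higher and 181 at least 2-fold lower than replicates 2 and 3, of 1456. Its distance to the nearest group was 2.32 times the largest distance between replicates 2 and 3 of any group, which argues against the label of another of the 6 groups. Its total count ranked 9 of 18 from the lowest, which argues against lower depth. No biological explanation was tested, and an exchange with a library outside the series stays open.

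For comparisons of 3 libraries with 3, 10 splits are too few for a share under 0.05. Salinity 383 against control at 12 h gave 467 features and the highest other split gave 0, so 1 of 10 splits reached the real count. At 18 h the real count was 0 and the highest other 392, for the split that set replicate 1 of salinity 383 with replicates 2 and 3 of control and replicate 1 of control with replicates 2 and 3 of salinity 383, which points to a structure of the samples. The real count was 0 so that all 10 splits reached it by construction, for salinity 293 at 12 h (highest other 0) and 18 h (highest other 1), for salinity 383 against 293 at 12 h and 18 h (0 and 0) and for control between times (0). For salinity 293 at 18 h and 383 against 293 at 12 h, where same-numbered deviations correlated through replicate 1, the 4 splits that part every pair gave 0 each in the fit without a block. With the replicate number as a block in the 2-group fit, the real splits gave 183 and 206, and the highest of the other 3 gave 0 for both. These 4 splits are too few for a share under 0.05.

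For the contrasts over both times, 100 splits within times were used. For salinity 383 averaged, 1 of 100 splits, the real one, reached 762, a share under 0.05, and the highest other gave 631. This argues against chance only if the libraries are separate replicates with the right labels, which is not known. Chance is not argued against for salinity 293 averaged, where 5 of 100 reached the real count of 1 and the highest other gave 333. Each of the 4 other splits that reached it set replicate 1 of control at 18 h apart from replicates 2 and 3 of that group. The split with 327 left the libraries at 12 h as labelled, and those with 333, 324 and 159 also set replicate 1 of salinity 293 at 12 h with 2 control libraries. Counts so far above the real one point to a structure of the samples. For the differences between times, the real count was 0, so that all 100 splits reached it by construction and the splits decide nothing. The highest others gave 333 for salinity 293 and 742 for salinity 383, but a split that exchanges control and treated labels at one time turns a response common to both times into a difference between them.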
